A study of Homo sapiens with 9 samples.

How the data were processed

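RNA was measured in MCF-7, an estrogen receptor-positive luminal breast cancer line, after 24 h with phosphate-buffered saline (PBS), with exosomes of MDA-MB-231 (231 exo) or with exosomes of MDA-MB-231/H1 (231/H1 exo). MDA-MB-231 is a mesenchymal-like, triple-negative breast cancer line. Per the labels, each group had 3 libraries, so that 9 libraries were compared, all made by SMART-Seq2 from polyA RNA. The columns of the 231/H1 exo group are headed NME1 in the count table, after the gene that encodes Nm23-H1. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

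Per the submitters' processing notes, cutadapt, STAR and DESeq2 were used with build hg38. Versions, settings, the counter, its annotation and any use of strand are not stated. The authors deposited raw counts per gene symbol (26475 genes, whole numbers in every library), and these were the input of every test. A second deposited table holds a processed signal of 11819 genes, in counts rescaled to a common library size by the authors. Its values lay within 1% of a constant multiple of the raw counts for at least 97.8% of the genes in each library. The largest deviation was 0.0186 on the log2 scale over 9654 genes with at least 100 counts. Its name speaks of a batch step, but no change beyond one factor per library was visible at that tolerance. It kept the genes above 1 CPM (counts over the library's total counts, rescaled) in at least 8 libraries, and 18 of its symbols had turned into dates. The authors also deposited tables of selected genes for the 3 comparisons, with a fold change (ratio), a log2 fold change, a p-value and an adjusted p-value per the file headers. The settings behind these are not stated. They were set beside the fit and entered no test.

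Libraries held 24436172 to 41244617 counts (median 28335637). Genes were kept with edgeR's filterByExpr by group, which left 14385 genes. The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, robust dispersion and robust shrinkage, in 1 fit of all 9 libraries with a mean per group. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene was called below 0.05 with no minimum fold. The common dispersion was 0.00958, a biological coefficient of variation of 9.79%. Standard errors of log2 fold changes were computed from the fold change and its F value and are approximate. CPM values of genes in the results are counts over the TMM-scaled library size of the genes kept, given as mean and SD over 3 libraries. Fold changes of the fit carry a small prior count.

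Gene lists were fixed before the data were examined, 37 in all, with 865 of 879 entries matched to the count table, 65 of them through an older symbol. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over 36 lists. None of the mitochondrially encoded genes was in the table, so that list is not analysed here. Each list result was repeated with the correlation estimated from the data and with fry. Members past the threshold were counted over all genes tested and adjusted over the list alone.

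The genes named were chosen by a rule set before the data were examined. Per comparison it takes the 12 called genes with the smallest p that rose and the 12 that fell, with a symbol and a mean of at least 1 CPM in either group. Where fewer than 5 pass in a direction the list is filled to 5 by smallest p, and those added are given as values. It adds NME1, NME2, the called members of each list or, where none was called, up to 2 with the smallest p, and 9 genes known to be regulated inversely to Nm23-H1. Values of added genes that were not called are not given in every comparison. Pseudogenes, unnamed loci and read-through genes were counted but not named. Coordinates are hg38 from GENCODE v44, to which 24545 symbols of the table matched.

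SMART-Seq2 does not mark the strand of a transcript, so reads of a gene and of a gene overlapping it on the opposite strand cannot be told apart. Of 201 named genes, 49 overlap another gene with at least 1 CPM, 46 of them on the opposite strand, and for 32 that gene's level is at least 10% of the named gene's. Counts of metallothioneins, hair keratins, histones, ribosomal proteins, FTH1, HSPA8 and KPNA2 are uncertain to the extent that the authors' counting split reads between near-identical copies.

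The gene tests and list tests were run on simulated data with the real means and library sizes. In these data 200 genes were changed, and the S phase list was raised 1.2-fold besides. The 200 genes were drawn from those above a minimum mean count, so the shares recovered do not cover the lowest counted genes. For 231 exo against PBS, edgeR recovered 14.9%, 56.7% and 84.8% of genes changed 1.2-, 1.5- and 2-fold, with 8.06% false calls. For 231/H1 exo against PBS the shares were 10.4%, 62.7% and 89.4%, with 7.56% false calls. For 231/H1 exo against 231 exo they were 17.9%, 64.2% and 83.3%, with 11.0% false calls. DESeq2's false calls in the same data were 15.5%, 17.7% and 14.9%. Changes near 1.2-fold were thus mostly missed at this depth and number of libraries.

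Alternatives tried were DESeq2 1.42.0, other scalings (RLE, upper quartile, total counts), no low-count filter or a 1 CPM filter, a replicate block, only the libraries of the groups compared, no robust shrinkage, a test against a 1.2-fold change, an adjusted p below 0.1, limma on the rescaled table and leaving out each library in turn. For the calls of genes and lists, only libraries of the groups compared were left out. A fit with the GC content and transcript length trend of each library removed, and a fit without 2 libraries, were added after seeing the data. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.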

Results

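The transcriptome of MCF-7 cells was profiled 24 h after PBS, 231 exo or 231/H1 exo, with 3 libraries per group. The stated question was how signaling downstream of 231 exo differs from that of 231/H1 exo, and 3 comparisons follow from it. Libraries held 28202652 to 41244617 counts with PBS, 24436172 to 28335637 with 231 exo and 27545484 to 33133047 with 231/H1 exo. Keratin 8 (KRT8), a luminal epithelial keratin, was the most counted gene in every library, at 1.43% to 2.28% of counts. Cytosolic ribosomal protein genes made up 2.90% to 3.16%. The 10 most counted genes made up 6.96% to 7.68% of counts, with means of 7.64% (PBS), 7.08% (231 exo) and 7.33% (231/H1 exo). For 231 exo against PBS, the libraries of the groups did not overlap in the share of the 10 most counted genes or in that of KRT8 (1.65% against 1.91%). In both, the two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow.

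NME1, the gene of Nm23-H1, stood at 113 ± 13.9 CPM with PBS, 113 ± 2.34 CPM with 231 exo and 106 ± 5.12 CPM with 231/H1 exo (mean ± SD, n = 3 each). It lies at chromosome 17, 51153559 to 51162428, plus strand. Its log2 fold change was −0.08 ± 0.0752 (SE) for 231/H1 exo against PBS (edgeR adjusted p = 0.748) and −0.08 ± 0.0755 against 231 exo (adjusted p = 0.716). The value for 231 exo against PBS was 0.00 ± 0.0753 (adjusted p = 0.999). NME2, which encodes the close paralog Nm23-H2, was listed at 0.949, 0.636 and 0.649 CPM in the same order and was called in no comparison. It overlaps the read-through gene NME1-NME2, which has 0 counts in all 9 libraries, and how reads of overlapping genes were counted is not stated, so these values may lie below the level of NME2 transcripts.

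**Figure D1:**
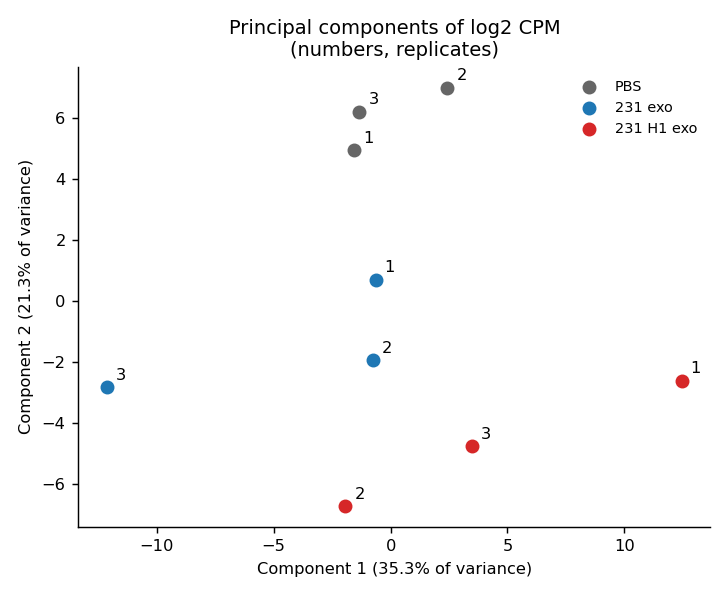
Principal components of log2 CPM over 6943 genes, component 1 (35.3% of variance) against component 2 (21.3%), each point a library numbered by replicate and coloured by group. PBS libraries lie at 4.94 to 7.0 on component 2 and the 231/H1 exo libraries at −6.72 to −2.61, while 231 exo replicate 3 (−12.1) and 231/H1 exo replicate 1 (12.5) stand apart on component 1.

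On the first principal component, 231 exo replicate 3 and 231/H1 exo replicate 1 stood apart from the other libraries, which lay between −1.93 and 3.48. Gene loadings on that component correlated with GC content across genes (Spearman 0.52, genes not being independent replicates). The trend of a library's deviations with GC content was −0.502 in 231 exo replicate 3 and 0.419 in 231/H1 exo replicate 1, but also 0.400 in PBS replicate 2 and −0.356 in 231/H1 exo replicate 2. The second component ordered the groups, with 231 exo (−2.81 to 0.70) between PBS and 231/H1 exo and overlapping the latter.

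The first comparison, 231 exo against PBS, asked what exosomes of the MDA-MB-231 line did to MCF-7. RRM2, which encodes a subunit of ribonucleotide reductase, the enzyme that makes deoxynucleotides for DNA synthesis, rose 1.3-fold, from 278 ± 7.67 to 362 ± 10.6 CPM (log2 fold change 0.38 ± 0.0461 SE, adjusted p = 0.00432, n = 3 each). SCD, the desaturase that makes monounsaturated fatty acids, fell 1.44-fold, from 908 ± 53.9 to 631 ± 36.2 CPM (adjusted p = 0.0144). The DNA replication genes were higher as a set, with a median log2 fold change of 0.18, and all 22 measured cholesterol synthesis genes lay below 0, with a median of −0.18. RRM2 lies at chromosome 2, 10120698 to 10211725, plus strand, and SCD at chromosome 10, 100347233 to 100364826, plus strand.

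Besides RRM2, 4 genes rose. PKIB, an inhibitor of cAMP-dependent protein kinase, reached 500 ± 17.7 CPM against 389 ± 10.9 (log2 fold change 0.36). BRIP1, a helicase that partners BRCA1 in DNA repair, reached 236 ± 12.3 against 181 ± 9.35 CPM (0.39). SFXN2, a mitochondrial carrier, reached 201 ± 9.76 against 157 ± 7.19 CPM (0.36), and KLHL4, a Kelch-like protein gene, 36.3 ± 1.95 against 23.5 ± 2.28 CPM (0.62). KRT81, a hair keratin expressed in some breast cancers, fell from 147 ± 10.7 to 103 ± 9.01 CPM (−0.51). The next genes by p on the lower side did not pass: CALML5 (−0.35, adjusted p = 0.051), the monoacylglycerol lipase gene MGLL (−0.45, adjusted p = 0.051) and KRT17 (−1.08, adjusted p = 0.0578). The body of MGLL overlaps SEC61A1 on the opposite strand.

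Among 30 S phase and E2F target genes, 1 rose over all genes tested (RRM2) and 17 adjusted over the list alone, with 27 above 0. The list passed camera (adjusted p = 6.97e-15) and kept an adjusted p = 0.00305 with an estimated correlation. None of the 22 cholesterol synthesis genes passed over all genes, and 7 were lower adjusted over the list alone. Its adjusted p was 1.41e-10, and 0.00511 with an estimated correlation. FDFT1, which encodes squalene synthase, had 199 ± 3.03 against 230 ± 2.36 CPM (log2 −0.21, adjusted p = 0.0957), and INSIG1, a brake on SREBP processing, 447 ± 30.3 against 535 ± 27.6 CPM (−0.26, adjusted p = 0.0957). Fatty acid synthesis genes had 1 fall (SCD) among 15 and 2 over the list alone, a median of −0.17 and an adjusted p = 6.32e-05 (adjusted p = 0.173 with an estimated correlation). No gene of the G2/M list passed over all genes and 5 of 25 were higher over the list alone (median 0.11, adjusted p = 9.16e-08, or adjusted p = 0.107 with an estimated correlation). In the TGF-beta list none of 19 passed and 4 were lower over the list alone (median −0.11, adjusted p = 0.000466, or adjusted p = 0.107 with an estimated correlation).

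Of the other lists, 6 passed camera in the lower direction, each without a called member. They were YAP and TEAD targets (median −0.09, adjusted p = 0.0016), epithelial junction and keratin genes (−0.11, adjusted p = 0.00237), focal adhesion and migration (−0.09, adjusted p = 0.00531), p53 targets (−0.04, adjusted p = 0.00531), autophagy and lysosome genes (−0.07, adjusted p = 0.0147) and immediate early and ERK feedback genes (−0.09, adjusted p = 0.0246). The list calls in the higher direction were ribosomal proteins (0.03, adjusted p = 0.00755), the unfolded protein response (0.06, adjusted p = 0.0134), nuclear oxidative phosphorylation (0.03, adjusted p = 0.0256), NF-kappaB genes (0.11, adjusted p = 0.027), heat shock genes (0.08, adjusted p = 0.0488) and 3 metallothioneins (0.23, adjusted p = 0.0488). With an estimated correlation none of these held, the smallest adjusted p = 0.185 and the largest adjusted p = 0.713.

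Leaving out single libraries ended 10 of these weaker calls. Without PBS replicate 1, ribosomal proteins and heat shock genes went to adjusted p = 0.3, metallothioneins to 0.102, NF-kappaB genes to 0.201, oxidative phosphorylation to 0.853, the unfolded protein response to 0.0878 and p53 targets to 0.0848. Without 231 exo replicate 2, ribosomal proteins went to 0.283, focal adhesion to 0.055, heat shock genes to 0.236, immediate early genes to 0.0625, metallothioneins and NF-kappaB genes to 0.201, and oxidative phosphorylation to 0.561. PBS replicate 2 (immediate early genes, 0.188), PBS replicate 3 (ribosomal proteins 0.0503, heat shock genes 0.0931, metallothioneins 0.105), 231 exo replicate 1 (heat shock genes 0.133, metallothioneins 0.0933, NF-kappaB genes 0.0505) and 231 exo replicate 3 (autophagy 0.11, immediate early genes 0.185, unfolded protein response 0.0904) ended others. The S phase, G2/M, cholesterol, fatty acid, TGF-beta, YAP and epithelial lists passed camera without any single library.

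The lists that did not pass in this comparison were MDA-MB-231 markers (adjusted p = 0.0609), NRF2 genes (0.153), Wnt targets (0.164), interferon response and nuclear-retained RNAs (0.391 each), endocytosis and estrogen response (0.463 each), histones (0.829), apoptosis regulators (0.837) and the genes regulated inversely to Nm23-H1 (0.88). ATF4 targets, leukocyte and fibroblast markers, glycolysis, hypoxia, the Nm23 family, Notch targets, exosome machinery, luminal markers and mesenchymal genes each had an adjusted p = 0.919. Some of these lists held members that passed adjusted over the list alone. Among them, 1 gene inverse to Nm23-H1 was higher and 1 lower, and 2 hypoxia genes were higher and 2 lower. Of the apoptosis regulators, 2 were higher and 1 lower. MDA-MB-231 markers passed, lower, without PBS replicate 1 (0.00992) or 231 exo replicate 3 (0.0318). Interferon genes passed, lower, without PBS replicate 2 (0.0107) or 231 exo replicate 2 (0.0189), and nuclear-retained RNAs without PBS replicate 2 (0.0485). Adjusted over the list alone, 2 of the 26 interferon genes were higher and 2 lower. ISG15 lay at 339 to 383 CPM against 281 to 304 CPM with PBS, and IFIT3 at 12.28 to 14.76 against 16.20 to 24.25 CPM. Neither was called. The median, mean and test of a list differed in sign for mesenchymal genes, the Nm23 family, the genes inverse to Nm23-H1, estrogen response, ATF4 targets, glycolysis, Notch targets and nuclear-retained RNAs. For the mesenchymal list the mean was 0.31 and the median −0.08, with the N-cadherin gene CDH2 at 0.641 ± 0.338 against 0.0196 ± 0.0178 CPM (adjusted p = 0.243).

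In all, edgeR's quasi-likelihood test called 7 of 14385 genes (5 rose, 2 fell), and for each of these the libraries of the groups did not overlap. In 15.6% of all genes they did not overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 1382 genes, and DESeq2 called 123 (72 higher, 51 lower). With RLE, upper quartile or total-count scaling 9 were called, 5 higher and 4 lower. The count was 3 without PBS replicate 2, 0 without PBS replicate 3 and 4 without 231 exo replicate 2, so none of the 7 was called every time a library was left out. With the GC and length trend removed 46 were called, 18 higher and 28 lower, so the balance of directions depended on the fit.

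The second comparison, 231/H1 exo against PBS, asked the same of exosomes from MDA-MB-231/H1. ID3, an inhibitor of basic helix-loop-helix transcription factors, fell 1.55-fold, from 272 ± 3.29 to 175 ± 4.23 CPM (log2 fold change −0.63 ± 0.0441 SE, adjusted p = 4.76e-06, n = 3 each), and its relatives ID2 and ID1 fell 1.49- and 1.69-fold. RRM2 rose 1.49-fold, to 414 ± 14.4 CPM (0.57 ± 0.0461, adjusted p = 1.76e-05). Genes of mitosis and DNA replication rose together, with 19 of 25 G2/M genes and 15 of 30 S phase genes called higher and none lower. The metallothionein gene MT2A, which encodes a small metal-binding protein, rose 1.89-fold, from 24.7 ± 2.39 to 46.8 ± 5.74 CPM. The interferon-induced antiviral genes MX1 and OAS2 rose 1.70- and 1.68-fold. ID3 lies at chromosome 1, 23557926 to 23559501, minus strand, and MT2A at chromosome 16, 56608584 to 56609497, plus strand.

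The genes with the smallest p that rose included, besides RRM2 and MT2A, BRIP1 (261 ± 13 against 181 ± 9.35 CPM), SFXN2 (214 ± 3.76 against 157 ± 7.19 CPM) and PKIB (502 ± 8.63 against 389 ± 10.9 CPM). CA2, carbonic anhydrase II, had 298 ± 8.07 against 228 ± 2.86 CPM, the kinetochore gene ZWINT 245 ± 5.20 against 185 ± 3.60 CPM and MT1X 14.4 ± 1.04 against 7.43 ± 0.138 CPM. Thymidine kinase 1 (TK1), the flap endonuclease FEN1, lamin B1 (LMNB1) and the nuclear import receptor KPNA2 rose by 0.43, 0.34, 0.63 and 0.27 on the log2 scale. The adjusted p of the 12 ranged from 1.76e-05 to 0.00136.

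The genes with the smallest p that fell included BCAS1, a gene amplified in some breast cancers, at 77.7 ± 1.01 against 125 ± 7.68 CPM (log2 −0.68, adjusted p = 8.92e-05). The hair keratins KRT81 and KRT86, near-identical and overlapping in position, had log2 values of −0.72 and −0.96. ITGB6, an integrin chain that activates latent TGF-beta, had −0.58, PMEPA1, a TGF-beta-induced feedback gene, −0.62, CYP24A1, the vitamin D 24-hydroxylase, −0.78, and RIN2, a RAB5 exchange factor, −0.68. CALML5 was at 61.4 ± 2.45 against 87.1 ± 0.462 CPM and the copper transporter gene SLC31A2, which overlaps FKBP15 on the opposite strand, at 64.1 ± 3.20 against 92.3 ± 2.38 CPM.

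**Figure D2:**
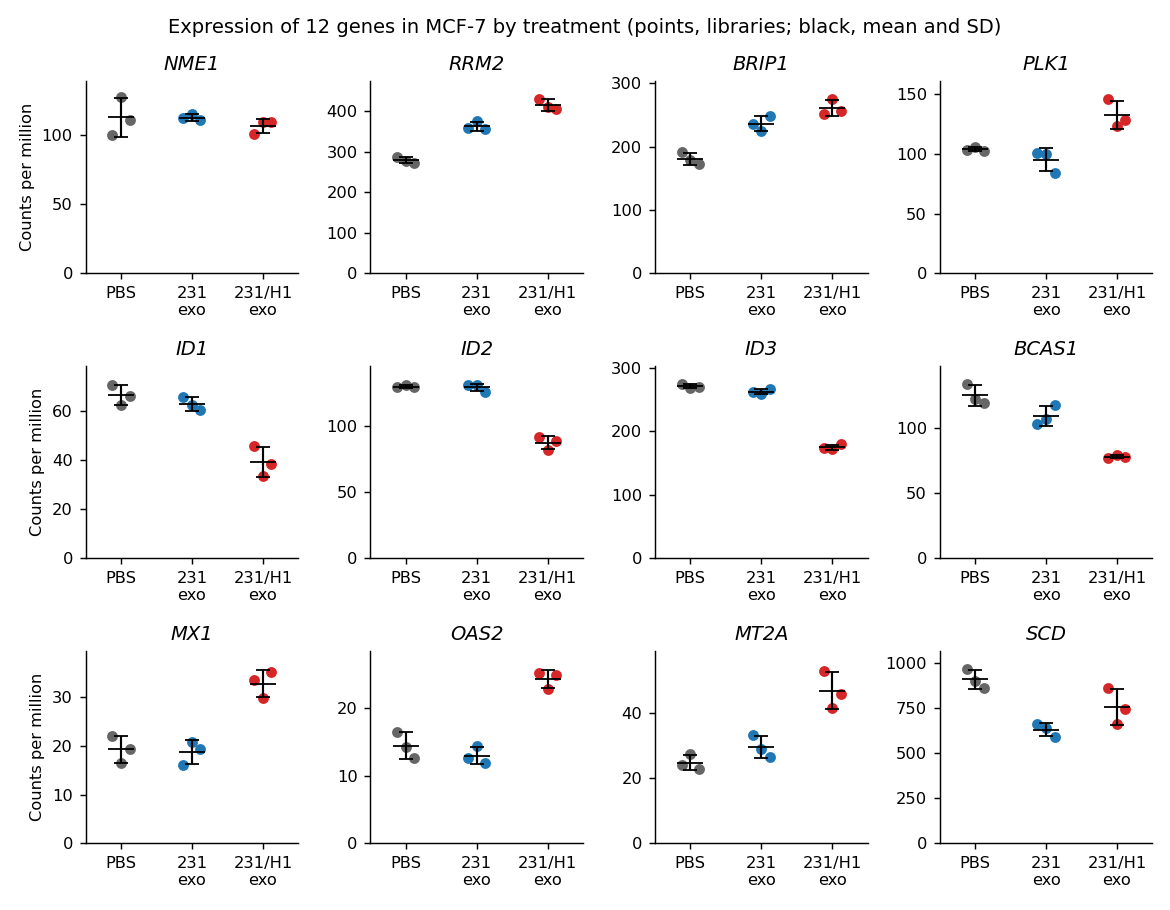
Expression of 12 genes in CPM (vertical axis, from 0) in the 3 libraries of each group (points), with the group mean and SD in black. ID3 sits near 272 and 263 CPM with PBS and 231 exo and at 175 CPM with 231/H1 exo, RRM2 steps from 278 to 362 to 414 CPM, SCD is lowest with 231 exo (631 CPM), and NME1 is at 106 to 113 CPM in every group.

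In the G2/M list, CDK1, the kinase that drives entry into mitosis, rose from 149 ± 6.26 to 201 ± 9.88 CPM, UBE2C from 123 ± 4.70 to 161 ± 4.57 CPM, HMMR from 61.8 ± 4.23 to 85.2 ± 3.94 CPM and the proliferation marker MKI67 from 97.4 ± 3.34 to 120 ± 3.69 CPM. All 25 members passed adjusted over the list alone, with a median log2 fold change of 0.30 (camera adjusted p = 1.02e-37, or adjusted p = 0.00186 with an estimated correlation). In the S phase list, the MCM helicase genes MCM3 and MCM5 rose by 0.26 and 0.45, PCNA by 0.27 and UHRF1 by 0.41 on the log2 scale. Adjusted over the list alone 24 were higher and 1 lower, with a median of 0.27 (adjusted p = 1.96e-32, or adjusted p = 0.000328 with an estimated correlation). CCNA2, DHFR, GINS1 and GINS2, also called higher, overlap other expressed genes on the opposite strand.

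In the TGF-beta list 8 of 19 fell, none rose, and 10 were lower over the list alone (median −0.57, adjusted p = 5.14e-27, or adjusted p = 0.00117 with an estimated correlation). They were ID1, ID2, ID3, PMEPA1, CDKN2B, TGFBI, SKIL and TGIF1. ID1 to ID3 are best known as targets of BMP signaling, and SKIL and TGIF1 encode repressors of SMAD signaling. CDKN2B, a cell cycle inhibitor induced by TGF-beta, went from 64.5 ± 1.14 to 42.6 ± 3.83 CPM (−0.60) and overlaps the antisense RNA CDKN2B-AS1. TGFBI went from 29.8 ± 2.91 to 19.3 ± 1.71 CPM (−0.62) and SKIL from 1014 ± 107 to 678 ± 74.1 CPM (−0.58).

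In the interferon list 6 of 26 rose and 14 were higher over the list alone, with a median of 0.32 (adjusted p = 1.42e-13, but adjusted p = 0.0866 with an estimated correlation). OAS3 rose from 25.1 ± 0.76 to 38.1 ± 4.10 CPM, ISG15, a ubiquitin-like modifier, from 294 ± 11.9 to 369 ± 8.08 CPM, IFIT1 from 87.8 ± 14.4 to 129 ± 4.32 CPM, and the transcription factor gene STAT1 from 432 ± 15.7 to 511 ± 14.7 CPM. MX1 overlaps TMPRSS2 and IFIT1 overlaps LIPA on the opposite strand. Of 3 metallothioneins tested, 2 rose and 3 were higher over the list alone (median 0.92, adjusted p = 5.31e-12, or adjusted p = 0.00481 with an estimated correlation). NF-kappaB genes had 2 rises among 15, NFKBIA (301 ± 12.9 to 367 ± 12.8 CPM) and the apoptosis inhibitor BIRC3 (1.15 ± 0.478 to 3.27 ± 0.72 CPM), and 3 over the list alone (median 0.29, adjusted p = 0.000724, or adjusted p = 0.0495 with an estimated correlation). The NF-kappaB call with an estimated correlation ended with the GC and length trend removed, and also without both libraries that stand apart on the first component.

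The following lists passed camera with the preset correlation and not with an estimated one. Glycolysis had 1 rise (LDHA, 0.21) among 19, all 19 above 0 and 7 over the list alone (median 0.17, adjusted p = 1.78e-05, or adjusted p = 0.262 with an estimated correlation). YAP and TEAD targets had 2 falls among 21, CTGF (−0.46) and NT5E (−0.54), with adjusted p = 0.000636 (adjusted p = 0.161 with an estimated correlation). Estrogen response genes had RERG (0.40) and TFF3 (0.30) higher and IGFBP5 (−0.36) lower among 26 (adjusted p = 0.00371, or adjusted p = 0.175 with an estimated correlation). Luminal markers had TFF3 and AGR2 (0.19) higher among 18 (adjusted p = 0.00371, or adjusted p = 0.214 with an estimated correlation). NRF2 genes had NQO1 (0.25), FTH1 (0.19) and AKR1C2 (0.25) higher among 22 (adjusted p = 0.00371, or adjusted p = 0.209 with an estimated correlation). MDA-MB-231 markers had TGFBI, ANXA3 (−0.30) and NT5E lower among 23, with 7 over the list alone (adjusted p = 0.0097, or adjusted p = 0.17 with an estimated correlation).

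The unfolded protein response had CRELD2 (0.38) and HSP90B1 (0.16) higher among 20 (adjusted p = 0.0111, or adjusted p = 0.161 with an estimated correlation), and CRELD2 overlaps ALG12. ATF4 targets had MTHFD2 (0.26) higher among 23 (adjusted p = 0.0186, or adjusted p = 0.175 with an estimated correlation). Cholesterol synthesis had FDFT1 (−0.20) lower among 22, with a median of −0.06 (adjusted p = 0.0254, or adjusted p = 0.158 with an estimated correlation). The list calls ended for cholesterol synthesis without PBS replicate 1 (0.0583) or 231/H1 exo replicate 2 (0.111) and for the unfolded protein response without the same libraries (0.0561 and 0.171). Without 231/H1 exo replicate 1, which stood apart on the first component, those of ATF4 targets (0.0916), estrogen response (0.0541) and luminal markers (0.0687) ended.

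Some lists did not pass as a set but held called genes. These were p53 targets (TP53INP1 −0.38 and BTG2 −0.40, list adjusted p = 0.0649), ribosomal proteins (RPL18A −0.16, 0.0865), heat shock genes (DNAJA1 0.24, HSPA8 0.18 and HSPB1 −0.26, 0.245), histones (HIST1H2BJ 0.48, 0.29), oxidative phosphorylation (SDHC 0.44, 0.483), mesenchymal genes (TGFBI, 0.483), Notch targets (HES1 −0.79, 0.485), apoptosis regulators (PMAIP1 0.38 and BIRC3, 0.659) and hypoxia (BNIP3 0.26, PDK1 0.51 and PFKFB3 −0.56, 0.985). TP53INP1 overlaps NDUFAF6. The list of genes inverse to Nm23-H1 (0.483) had CTGF, a matricellular growth factor gene also called CCN2, lower at 42.3 ± 4.16 against 58.1 ± 6.28 CPM (adjusted p = 0.0192). Its other tested members were not called: MET 0.26 (adjusted p = 0.299), NETO2 −0.16, FZD1 0.07, L1CAM −0.08 and LPAR1 0.08. PTN, SMO and MMP2 were too low to be tested. After 231 exo CTGF was not called, but its libraries (40.7 to 47.2 CPM) lay below those of PBS (51.1 to 63.3 CPM). Its libraries of 231/H1 exo lay at 39.5 to 47.1 CPM.

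No member was called in focal adhesion (adjusted p = 0.128), immediate early genes (0.226), endocytosis (0.288), Wnt targets (0.326), nuclear-retained RNAs and the Nm23 family (0.355 each), epithelial junction genes (0.483), leukocyte and fibroblast markers (0.625), autophagy (0.641), or fatty acid synthesis and exosome machinery (0.726 each), and none of these lists passed. Without 231/H1 exo replicate 1, ribosomal proteins (0.00337), epithelial junction genes (0.0254), focal adhesion (0.0131), immediate early genes (0.0277) and p53 targets (0.0217) passed in the lower direction. Ribosomal proteins also passed without PBS replicate 1 (0.00496) or 3 (0.0327), and p53 targets without PBS replicate 2 (0.018). Median, mean and test differed in sign for mesenchymal genes (median 0.01, mean 0.23, lower by camera), epithelial junction genes, hypoxia, fatty acid synthesis, nuclear-retained RNAs, endocytosis and autophagy.

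The edgeR test called 333 genes, 229 higher and 104 lower, and the groups' libraries did not overlap in any of them. Across all genes 18.5% did not overlap, against 10% by chance, and 1790 genes had an unadjusted p under 0.05. Most changes were small: the median fold was 1.31, with 59 genes at least 1.5-fold and 8 at least 2-fold. Tested against a 1.2-fold change, 18 were called, 5 higher and 13 lower, so the surplus of higher genes did not extend to these. DESeq2 called 605 (381 higher, 224 lower) and edgeR with the GC and length trend removed 508. The count was 191, 164 and 125 without PBS replicate 1, 2 or 3, and 210 and 104 without 231/H1 exo replicate 2 or 3. Of 95 named gene calls, 39 held every time a library of the groups compared was left out, ID1, ID2, ID3, RRM2, MT2A, MX1 and OAS2 among them.

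The third comparison set the exosome preparations against each other, which is the series' question. ID3, ID2 and ID1 were lower after 231/H1 exo than after 231 exo, by 1.5-, 1.48- and 1.60-fold (ID3 175 ± 4.23 against 263 ± 4.07 CPM, log2 −0.58 ± 0.0442 SE, adjusted p = 1.49e-05, n = 3 each). Interferon-induced genes were higher, with OAS2 at 24.3 ± 1.3 against 13 ± 1.28 CPM (0.90 ± 0.121, adjusted p = 0.00533) and MX1 at 32.8 ± 2.76 against 18.8 ± 2.40 CPM (0.80 ± 0.122, adjusted p = 0.0107). PLK1, a mitotic kinase, was 1.40-fold higher (133 ± 11.9 against 95.0 ± 9.65 CPM, adjusted p = 0.0164), and the metallothionein genes MT2A and MT1X were 1.58- and 1.65-fold higher. OAS2 lies at chromosome 12, 112978395 to 113011723, plus strand, and MX1 at chromosome 21, 41420020 to 41470071, plus strand.

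The other genes that rose were IFIT1 (0.69), OAS1 (0.51) and XAF1 (1.28; 5.53 ± 0.704 against 2.28 ± 0.566 CPM) of the interferon list, TMED9, a secretory pathway cargo receptor gene (0.46), KPNA2 (0.23), PRC1, an organizer of the mitotic spindle midzone (0.28), and STYK1 (1.05; 6.08 ± 0.834 against 2.92 ± 0.562 CPM). Those that fell were GSTM3, a glutathione S-transferase (344 ± 23.1 against 468 ± 24.5 CPM), BCAS1 (−0.49), CYP24A1 (−0.66), the small heat shock protein gene HSPB1 (4431 ± 121 against 5305 ± 138 CPM), ITGB6 (−0.37), RHOBTB3 (−0.44), RIN2 (−0.49), RAB31 (−0.35) and PMEPA1 (−0.39). SHISA2 (−0.51) also fell, and was named only after its values were seen.

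In the interferon list 5 of 26 rose and 13 were higher over the list alone, 23 lay above 0 and the median was 0.45 (adjusted p = 5.9e-20, or adjusted p = 0.0378 with an estimated correlation). In the TGF-beta list 4 of 19 fell, ID1, ID2, ID3 and PMEPA1, and 6 were lower over the list alone (median −0.33, adjusted p = 1.86e-15, or adjusted p = 0.0117 with an estimated correlation). All 25 G2/M genes lay above 0, with 1 rise (PLK1) over all genes and 17 over the list alone (median 0.18, adjusted p = 1.16e-17, or adjusted p = 0.0148 with an estimated correlation). No S phase gene passed over all genes and 5 of 30 were higher over the list alone (median 0.14, adjusted p = 3.58e-07, or adjusted p = 0.0147 with an estimated correlation). TK1, the first of them by p, had 189 ± 7.94 against 155 ± 8.18 CPM (adjusted p = 0.0644). Metallothioneins had 2 rises among 3, and 2 over the list alone (median 0.66, adjusted p = 1.05e-07, or adjusted p = 0.0173 with an estimated correlation).

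Cholesterol synthesis genes were higher as a set, with none called over all genes and 5 of 22 over the list alone (median 0.07, adjusted p = 0.000961, or adjusted p = 0.0408 with an estimated correlation). LDLR, the LDL receptor gene, had 61.6 ± 7.32 against 47.5 ± 1.24 CPM (0.37, adjusted p = 0.119). The libraries that stand apart on the first component, 231 exo replicate 3 and 231/H1 exo replicate 1, both enter this comparison. Without both, the median of the Interferon response list was 0.33, that of TGF-beta response −0.30, that of G2/M cell cycle 0.21, that of S phase and E2F targets 0.10, that of Metallothioneins 0.49 and that of Cholesterol synthesis 0.07, and each passed camera with the preset correlation. With an estimated correlation and without both, the G2/M list alone passed (adjusted p = 0.0348). The calls of TGF-beta response (adjusted p = 0.0561), S phase and metallothioneins (0.0743 each), cholesterol synthesis (0.11) and interferon response (0.171) were lost.

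**Figure D3:**
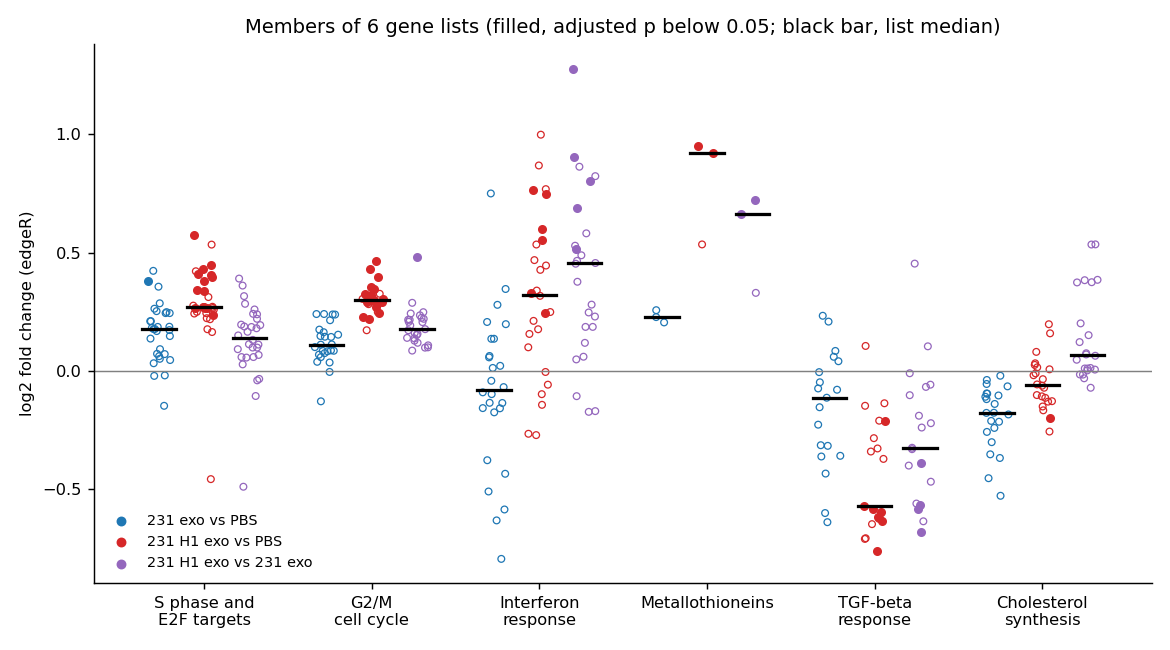
Log2 fold changes (vertical axis) of the members of 6 gene lists in the 3 comparisons (colours), filled where the edgeR adjusted p was below 0.05, with a bar at each list's median. TGF-beta medians are −0.11, −0.57 and −0.33, interferon medians −0.08, 0.32 and 0.45, and cholesterol synthesis medians −0.18, −0.06 and 0.07 for 231 exo against PBS, 231/H1 exo against PBS and 231/H1 exo against 231 exo.

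The remaining calls with the preset correlation, 7 in number, did not hold with an estimated one. They were ribosomal proteins, lower (median −0.06, adjusted p = 1.41e-06, or adjusted p = 0.479 with an estimated correlation), glycolysis, higher (0.14, adjusted p = 5.91e-06, or 0.34), fatty acid synthesis, higher (0.14, adjusted p = 0.000585, or 0.225), and luminal markers, higher (0.12, adjusted p = 0.00192, or 0.277). Estrogen response (0.11, adjusted p = 0.0288, or 0.34), ATF4 targets (0.09, adjusted p = 0.0288, or 0.277) and epithelial junction genes (0.10, adjusted p = 0.0488, or 0.602) were higher too. The last 3 calls also ended with single libraries left out. Without 231/H1 exo replicate 1 the adjusted p was 0.22, 0.166 and 0.456 in that order, and without 231 exo replicate 3 it was 0.0528, 0.0963 and 0.243. Without 231/H1 exo replicate 3, ATF4 targets were at 0.051 and epithelial junction genes at 0.0506, without 231 exo replicate 2 estrogen response was at 0.141 and epithelial junction genes at 0.0574, and without 231 exo replicate 1 ATF4 targets were at 0.0597.

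The other lists did not pass. They were autophagy (adjusted p = 0.104), NRF2 genes (0.132), NF-kappaB genes (0.186), oxidative phosphorylation (0.317), MDA-MB-231 markers (0.475), mesenchymal genes and the Nm23 family (0.501 each), focal adhesion (0.508), leukocyte and fibroblast markers (0.535), histones (0.551), immediate early genes, Notch targets and YAP targets (0.637 each), p53 targets (0.688), the genes inverse to Nm23-H1, endocytosis and heat shock genes (0.723 each), the unfolded protein response (0.768), exosome machinery (0.88), Wnt targets (0.904), nuclear-retained RNAs and hypoxia (0.907 each) and apoptosis regulators (0.927). HSPB1 was the only called gene among them. Median, mean and test differed in sign for p53 targets, MDA-MB-231 markers (median −0.03, mean 0.11, lower by camera), nuclear-retained RNAs, endocytosis, exosome machinery, Notch targets and apoptosis regulators.

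In this comparison edgeR called 25 genes, 12 higher and 13 lower, with no overlap between the groups' libraries in any of them. Across all genes 14.5% did not overlap, against 10% by chance, and 1664 genes had an unadjusted p under 0.05. Of the 25, 20 were also called in the same direction for 231/H1 exo against PBS, but both comparisons use the same 231/H1 exo libraries, which alone makes for shared calls, and the number to be had without an effect was not simulated. The others were OAS1, XAF1, STYK1, RAB31 and SHISA2. For the last 3, log2 values against PBS were 0.48, −0.07 and −0.21 after 231/H1 exo. After 231 exo they were larger in size, at −0.57, 0.28 and 0.30, and not called. None of the 25 was among the 7 called by edgeR for 231 exo against PBS, which is a short list. The folds at 1.5 or more numbered 9. DESeq2 called 144 (89 higher, 55 lower). The count was 10 without 231 exo replicate 1, 13 without 231 exo replicate 3, and 14, 44 and 3 without 231/H1 exo replicate 1, 2 or 3. It was 11 without both libraries that stand apart. ID2, ID3 and GSTM3 were called every time a library of the groups compared was left out.

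Set side by side, the comparisons against PBS shared 6 called genes, RRM2, PKIB, SFXN2, BRIP1 and KLHL4 higher and KRT81 lower. Independent lists of those sizes would share 0.0796 higher and 0.0145 lower, and simulated unchanged groups with shared PBS libraries gave 0.01 and 0 on average. Almost no gene is called in such groups, so this simulation cannot show how many shared calls the shared PBS libraries bring about. Log2 fold changes correlated across 14385 genes with r = 0.492, against 0.488 ± 0.0131 in simulations without any effect, since both comparisons use the same PBS libraries. The covariance was 0.0433 against 0.0320 simulated, a difference of 0.0114, whereas the share of genes with the same sign, 64.9%, was below the simulated 66.5% ± 0.417%. The 3 PBS libraries cannot be split into groups of at least 2, so part of the shared calls and of the excess in covariance may come from the shared controls. The overlap was 3 without PBS replicate 2, 0 without PBS replicate 3, 12 without 231/H1 exo replicate 1 or replicate 2, and 3 without 231/H1 exo replicate 3.

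The authors' tables list genes with an adjusted p below 0.05 and a fold of at least 1.2. They hold 127 genes for 231 exo against PBS (40 higher, 87 lower), 449 for 231/H1 exo against PBS (268 higher, 181 lower) and 107 for 231/H1 exo against 231 exo (68 higher, 39 lower). The edgeR fit called 7, 250 and 21 of them in the same direction, and all tested ones had the same sign. Across these genes, which are not independent replicates, log2 fold changes correlated at r = 0.974, 0.967 and 0.985, and the authors' values were 0.742, 0.828 and 0.777 times those of the fit (median).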

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

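The comparisons, lists and alternatives were chosen before the data were examined, except the removal of the GC and length trend and the fit without 231 exo replicate 3 and 231/H1 exo replicate 1, which, alone or with an estimated correlation between genes, were chosen after seeing the data. For 231 exo against PBS, 231/H1 exo against PBS and 231/H1 exo against 231 exo, edgeR called 7, 333 and 25 genes and DESeq2 123, 605 and 144, over the 9086, 12154 and 8249 genes it kept. DESeq2 called 7, 329 and 23 of the edgeR genes in the same direction and had not tested 4 and 2 of the rest. An adjusted p below 0.1 gave 39, 518 and 44, which follows from the threshold, and a test against a 1.2-fold change 0, 18 and 2. With the GC and length trend removed there were 46, 508 and 53, among them 7, 326 and 23 of the original genes. No low-count filter gave 55 (231 exo against PBS) and 52 (231/H1 exo against 231 exo), and fitting only the groups compared gave 14 and 10. Without both libraries that stand apart, 231/H1 exo against 231 exo had 11, of which 8 were among the 25. Of the 24 named among these, OAS2 went from 0.90 to 0.82 (adjusted p = 0.0366), MX1 from 0.80 to 0.81 (adjusted p = 0.0504) and IFIT1 from 0.69 to 0.68 (adjusted p = 0.211), so the calls of MX1 and IFIT1 ended at similar changes with fewer libraries, while MT2A went from 0.66 to 0.49 (adjusted p = 0.171) and PLK1 from 0.48 to 0.33 (adjusted p = 0.0667). RLE, upper quartile and total-count scaling, a 1 CPM filter, no robust shrinkage and limma on the rescaled table kept each count within 1.5 times. No called gene changed sign under any of these. Except where a reason is given, the cause was not tested.

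Leaving out single libraries gave 0 to 6, 104 to 265 and 3 to 44 calls. The counts outside 1.5 times were 3, 0 and 4 without PBS replicate 2, PBS replicate 3 or 231 exo replicate 2 (231 exo against PBS). They were 191, 164, 125, 210 and 104 without PBS replicates 1, 2 and 3 or 231/H1 exo replicates 2 and 3 (231/H1 exo against PBS). For 231/H1 exo against 231 exo they were 10, 13, 14, 44 and 3 without 231 exo replicates 1 and 3 or 231/H1 exo replicates 1, 2 and 3. The labels number the replicates but do not say that the numbers pair. Deviations from the group mean, over genes with a mean log2 CPM above 4, were correlated between libraries of different groups. The values were −0.246 to 0.406 for libraries of the same number and −0.572 to 0.444 for libraries of different numbers. Treating the number as a block gave 11, 320 and 27 calls.

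Of the gene lists, 17, 15 and 13 passed camera with the preset correlation and 2, 5 and 6 with an estimated one. The latter became 2, 4 and 6 with the GC and length trend removed, and 2, 4 and 1 without both libraries that stand apart, where the NF-kappaB call of 231/H1 exo against PBS ended in both (adjusted p = 0.051 and 0.121). With fry the count was 6 for 231 exo against PBS and 6 for 231/H1 exo against 231 exo. For 231/H1 exo against PBS it stayed within 1.5 times the camera count, with interferon response at a fry adjusted p = 0.0233 and glycolysis at 0.0599. Leaving out libraries gave 11 to 18, 13 to 17 and 10 to 13 lists, with 11 both without PBS replicate 1 and without 231 exo replicate 2, and the block 15, 15 and 13. The list Epithelial junction and keratin genes, higher for 231/H1 exo against 231 exo, turned lower without both libraries that stand apart (adjusted p = 0.901). Over the alternatives other than these pairs of choices, list results stayed on their side of the threshold 1152 times. They lost the threshold 118 times, gained it 25 times and reversed 1 time. For named genes the counts were 4998, 506, 153 and 0, in that order. Reversals were counted only for lists called in the main fit and for genes called in either fit. Results uncalled in both fits that changed sign thus count as having stayed.

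The comparisons against PBS shared 6 calls, 32 at an adjusted p below 0.1, 82 with DESeq2, 36 without a low-count filter, 34 with the GC and length trend removed, 9 with the block and 0 to 12 with single libraries left out (3 without PBS replicate 2 or 231/H1 exo replicate 3, 0 without PBS replicate 3, 12 without 231/H1 exo replicate 1 or 2). The correlation of their fold changes, 0.492, was 0.468 in genes of at least 10 CPM, 0.430 without both libraries that stand apart, 0.498 with the block and 0.434 to 0.627 with single libraries left out. Of the genes in the authors' tables, 7, 250 and 21 were called in the same direction, 66, 384 and 85 with DESeq2, 10, 233 and 22 with the block, and 21 and 32 at an adjusted p below 0.1 for 231 exo against PBS and 231/H1 exo against 231 exo. NME1 was called under no alternative, with log2 values of −0.09 to 0.10, −0.17 to 0.01 and −0.11 to −0.04 as single libraries were left out. Shares of ribosomal protein and histone counts without the 10 most counted genes kept every p at 0.2 or above. At this depth and number of libraries, changes near 1.2-fold were mostly missed in simulated data.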

Other observations

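All gene families and all tests of this part were chosen after the results were seen, except the count of other splits of the libraries, which was planned. With 3 libraries per group there are 10 splits of 6 libraries, too few for a share under 0.05. The real split called 7, 333 and 25 genes in the comparisons' order, the highest of the other splits called 0, and 1 split, the real one, gave as many. Among 22 keratins, 5 fell after 231/H1 exo against PBS and none rose. KRT80 went from 141 ± 11.8 to 76.8 ± 17.2 CPM (log2 −0.88, adjusted p = 0.00425), KRT83 from 7.69 ± 1.27 to 3.54 ± 0.581 CPM (−1.12, adjusted p = 0.0044) and KRT7 from 28.8 ± 1.13 to 21.9 ± 1.71 CPM (−0.40, adjusted p = 0.0308), beside KRT81 and KRT86. KRT8 (19016 ± 494 to 19802 ± 2646 CPM) and KRT18 (7694 ± 95.4 to 7516 ± 523 CPM) were not called. The family's median was −0.18 (camera p = 2.44e-08, or 0.0257 with an estimated correlation, neither adjusted). It was −0.26 after 231 exo, where KRT81 alone was called (camera p = 1.57e-11, or 0.0112 with an estimated correlation), and −0.15 there without both libraries that stand apart. Between the exosome groups it was 0.04 (camera p = 0.793, or 0.894 with an estimated correlation). The reads of KRT81, KRT83 and KRT86, close paralogs in the type II cluster, may be shared. KRT86 also overlaps KRT7 on the same strand.

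Annexins and S100 proteins, calcium-binding families of membranes and the cytoskeleton, had 5 falls among 22 after 231/H1 exo against PBS. ANXA2 went from 1764 ± 92.2 to 1386 ± 49.6 CPM (−0.35, adjusted p = 0.00157), its partner S100A10 from 603 ± 16.2 to 485 ± 15.5 CPM (−0.31, adjusted p = 0.00131) and S100P from 31.5 ± 0.876 to 22.5 ± 2.46 CPM (−0.49, adjusted p = 0.011). The median was −0.14 (camera p = 1.55e-05, or 0.0549 with an estimated correlation). After 231 exo it was −0.09 with no member called (camera p = 0.000532, or 0.103 with an estimated correlation). Between the exosome groups it was −0.02 (camera p = 0.142, or 0.445 with an estimated correlation). Families of the mitotic apparatus, some of whose members are also in the G2/M list, had members that rose after 231/H1 exo against PBS. Centromere proteins had 5 rises among 19 (CENPN 139 ± 3.43 to 172 ± 5.21 CPM, median 0.30, camera p = 2.14e-13, or 0.000206 with an estimated correlation). Kinesins had 6 among 30 (KIF4A 41.3 ± 2.22 to 55.7 ± 3.80 CPM, median 0.15, camera p = 4.5e-05, or 0.00969 with an estimated correlation). Tubulins had 3 among 15 (TUBA1B 1138 ± 4.77 to 1525 ± 157 CPM, median 0.26, camera p = 0.00265, or 0.129 with an estimated correlation).

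S phase and G2/M genes were higher after 231/H1 exo than after PBS, with a median log2 fold change of 0.29 over 55 members. With the GC and length trend of the libraries removed the median was 0.28 (unadjusted camera p = 1.12e-05 with an estimated correlation), and without the libraries that stand apart it was 0.30 (camera p = 3.14e-05). Both argue against these as the whole cause. A difference between exosome preparations or in culture density coincides with the groups and cannot be told apart from an effect of the treatment.

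Interferon genes were higher after 231/H1 exo than after 231 exo, with a median of 0.45 over 26 members (camera p = 0.00525 with an estimated correlation, adjusted p = 0.0378), and 0.42 with the GC and length trend removed (p = 0.0057, adjusted p = 0.0359), which argues against that trend. RNA of the donor cells would bring their abundant transcripts. VIM, LGALS1 and CD44 together differed by 1.56 CPM (SE 4.11), against a summed gain of 213 CPM (SE 94.3) in interferon genes. Both donors are of the MDA-MB-231 line, so equal carry-over would leave no difference in these markers. Whether the donors differ in interferon transcripts was not measured, so these values address only unequal carry-over. Against PBS (153 to 162 CPM) these markers, none of them called, summed higher in each library of 231 exo (164 to 170 CPM) and 231/H1 exo (163 to 175 CPM). Chance gives such a separation in 10% of comparisons. VIM stood apart from PBS (22.2 to 23.7) after 231 exo (26.2 to 28.6) but not after 231/H1 exo (22.3 to 25.1). LGALS1 lay above every PBS library in both groups, and CD44 overlapped PBS in both. The fixed list of MDA-MB-231 markers, which includes them, leaned lower. Of its 23 members, 15 lay below 0 after 231 exo (camera adjusted p = 0.0609) and 14 after 231/H1 exo (adjusted p = 0.0097). A small carry-over of donor RNA into both groups stays open. Without the libraries that stand apart the median was 0.33 with quartiles of 0.0788 and 0.674, and the list call with an estimated correlation was lost (p = 0.0285, adjusted p = 0.171) as the median fell and fewer libraries were left, so their part stays open. The summed interferon genes of 231 exo replicate 2 (2227 CPM) came close to the 231/H1 exo libraries (2246 to 2311 CPM). Replicates 1 and 3 of 231 exo summed to 1911 and 2031 CPM, and the PBS libraries to 1903 to 1914 CPM. A difference between exosome preparations coincides with the groups and cannot be told apart from an effect of the treatment.

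Cholesterol synthesis genes were lower after 231 exo than after PBS, with a median of −0.18 over 22 members. It was −0.16 with the GC and length trend removed (unadjusted camera p = 0.000169 with an estimated correlation) and −0.17 without the libraries that stand apart (camera p = 0.00111), which argues against both as the whole cause. A difference in exosome preparation or culture conditions coincides with the groups and cannot be told apart from an effect of the treatment.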
